A study of Apera spica-venti with 2 samples.

How the data were processed

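Leaf RNA came from 1 susceptible and 1 resistant sample of Apera spica-venti. Per the labels' protocols, plants were grown in a greenhouse at 16 or 21 °C and sprayed at growth stage 12 to 13 of the BBCH scale. The doses were 10 g per hectare of iodosulfuron-methyl sodium, 9 of pyroxsulam, 45 of pinoxaden or 69 of fenoxaprop-P-ethyl. The first pair inhibits ALS and the second pair ACCase. Untreated plants were the controls, and leaves were taken 3 and 7 days after spraying. Which treatment and day entered each of the 2 libraries is not stated in the labels. Libraries were made from 100 ng of total RNA with a stranded kit that removes plant ribosomal RNA.

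The 1 table analysed lists, for each predicted protein of the assembly, its name, the accession and description of its match, its length, the number of matches kept, the E-value and the mean similarity. Sequence names have the form that the Trinity assembler writes. The column of similarity is in percent as deposited, per the file headers, and length is taken as residues of the predicted protein. The number of matches kept was 1 for every protein, and the highest E-value was 0.001. The aligner, the protein database and any filters are not given in the sources used here. The table pools both samples. Values per sample, bit scores, percent identity, aligned length and organism names were not used here, so no level, fold change or organism make-up was computed, and depth is unknown. No genome was used, and no coordinates are given.

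A total of 18 gene lists, written before the data were examined, were matched to the descriptions without regard to case. No predicted protein fell in 2 lists. A name counted as telling unless it was of the unnamed, predicted, hypothetical, unknown or uncharacterized kind or a bare locus name. Shares carry exact (Clopper-Pearson) 95% binomial intervals. The planned comparison of percent identity was made on similarity instead. Each list's median was compared with that of all other predicted proteins by a two-sided permutation test with 100000 resamples. For lists under 10 proteins, every possible list of that size was counted instead, by the distance of its median from the median of all proteins (exact permutation test). The Benjamini-Hochberg adjustment ran over the 18 lists, with a threshold of 0.05. Intervals of the differences came from 2000 bootstrap samples of the list.

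The accessions named were taken from those given by a rule fixed in advance. In each list the rule gave the 2 accessions matched by the most predicted proteins and the 2 with the strongest match, and for the target lists every accession. Over the whole table it gave the 10 matched by the most proteins. The rule asked for the bit score, for which the lowest E-value was used, with ties broken by the longer predicted protein. Families within lists, such as CYP71 or RGA4, were chosen after their values were seen.

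On simulated data, lists drawn at random from the 39502 proteins gave p under 0.05 in 7.5% of 200 draws at 30 proteins per list, 8.0% at 100 and 2.5% at 400. With a shift of -5 points planted, 32.5%, 78.5% and 100% of lists of these sizes were called, so a difference of that size would often be missed in a list of 30. These draws used fewer resamples, an unadjusted p, independent members and a downward shift only. The rates therefore do not carry over directly to the adjusted calls. The exact count was checked against full enumeration on small sets. Alternatives covered stricter E-values of 1e-20 and 1e-50, a similarity of at least 50%, a length of at least 200 residues, each assembly gene or each matched accession counted once by its strongest match, corrected list names, a background of proteins with telling names, and the removal of accession runs that hold fungal locus tags. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0.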

Results

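Leaf RNA of Apera spica-venti, the silky bent-grass weed of cereal fields, was sequenced from 1 herbicide susceptible and 1 herbicide resistant sample, and the reads were assembled de novo. The title of the series asks which herbicide-responsive and plant-pathogen interaction pathways take part in resistance to inhibitors of acetyl-CoA carboxylase (ACCase), the enzyme that makes malonyl-CoA for fatty acid synthesis. The table used here lists the protein matches of the assembly as a whole and holds no value for either sample. Levels in resistant against susceptible plants were therefore not analysed here, and the sequencing depth of each sample is unknown. What follows describes which genes of the named pathways the assembled leaf transcriptome holds and how closely they match known proteins.

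The table named 39502 predicted proteins on 29344 transcripts, each transcript being the only listed form of its assembly gene. Each protein had 1 match, with a similarity between 37.5% and 100% and a median of 85.1% (quartiles 73.3% and 93.1%). The predicted proteins were short, with a median of 196 residues and a range from 99 to 4892. A match with a telling name was found for 14591 of them, which is 36.9% (exact 95% interval 36.5% to 37.4%). The remaining 24911 matched entries such as unnamed or uncharacterized proteins, so members of a gene family among them are not counted below. The counts are of predicted proteins by name, not of genes, and names fixed in advance both missed spellings and took in neighbouring proteins. Named matches were also closer, with a median similarity of 89.6% against 81.8% for the rest. Intervals cover counting error only, and with 1 library per group there is no replicate error to set values against.

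The first question was whether the targets of the herbicides used on these plants were represented. Matches with names of both target enzymes were found. ACCase had 2 predicted proteins under the names fixed in advance and 1 more under another spelling. Acetolactate synthase (ALS), the first enzyme of branched-chain amino acid synthesis, had 4. The longer ACCase protein of the list had 2269 residues and was 96.4% similar to a cytosolic acetyl-CoA carboxylase 2 (QEG99472.1). The other had 142 residues and was 100% similar to a protein named acetyl-CoA carboxylase biotin (EPQ62564.1), whose accession lies in a run of 102 matches that also holds fungal locus tags. The further protein was found by reading the descriptions, not by the fixed names. It was the longest of the 3 at 2321 residues, lay in the same assembly cluster as the cytosolic one and was 98.3% similar to an acetyl-coenzyme A carboxylase (CAL63610.1). Its name does not say whether it is the plastid form, the one that ACCase inhibitors act on in grasses, or the cytosolic form. None of the 3 ACCase names gives the plastid form, so whether that target is present stays open. The catalytic ALS protein had 639 residues and was 99.5% similar to its match (ADM13378.1). The other 3 ALS proteins matched a chloroplast small subunit 2, the regulatory part of the enzyme, at 95.9% (XP_003572704.1), 93.4% (XP_020176401.1) and 90.5% (XP_020157681.1), and a pair of them lay on 1 transcript. The median similarity lay 13.1 points above that of the other proteins for the ACCase list and 9.53 points above for the ALS list, with 100% of the members of each above the others' median. Without the accession runs that hold fungal locus tags, the ACCase list kept 1 protein and was not tested. The two-sided exact permutation test gave an adjusted p of 0.2 for ACCase (n = 2) and 0.24 for ALS (n = 4). It could not have passed the threshold upward for lists this small, since the exact p with every member at 100% would be 0.11 and 0.058.

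The next question concerned the families that detoxify or move herbicides. The 8 herbicide lists together took 527 predicted proteins, 1.33% of the table (exact 95% interval 1.22% to 1.45%). UDP-glycosyltransferases, which attach sugars to small molecules, numbered 141 under the names fixed in advance, ABC transporters, the ATP-driven pumps of membranes, 129 and cytochrome P450 proteins, the oxidising enzymes of many herbicide breakdown routes, 120. With names corrected after the descriptions had been read the order turned over, to 172 P450 proteins, 134 ABC transporters and 97 glycosyltransferases. There were 86 hydrolases and esterases, 39 glutathione S-transferases and 6 aldo-keto reductases.

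Among the P450 proteins found under the names fixed in advance, the CYP71 names led with 25, at a median similarity of 87.4%. CYP89 followed with 12 and CYP72 with 11. The accessions matched most often were a cytochrome P450 (CCP37680.1) and a cytochrome P450 71D7 (KAE8791113.1), each by 4 predicted proteins, at 88.1% to 93.2% and 80.1% to 87.9%. The strongest matches were not P450 enzymes themselves but the reductases that pass electrons to them. Predicted proteins of 700 and 694 residues matched these reductases at 94.3% (CAC83301.1) and 94.4% (XP_020186523.1). Of the glutathione S-transferases, which join glutathione to reactive compounds, 13 carried a GSTU6 name, with a median of 82.1%. A chloroplast glutathione S-transferase 6 (KAE8808367.1) and a glutathione S-transferase F11 (XP_003558871.1) gave the strongest matches, at 96.9% and 97.3%, and a glutathione transferase (CAA09188.1) was the only accession of that list matched by 2 proteins.

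An anthocyanidin 3-O-glucosyltransferase 2-like protein (XP_020192474.1) was matched by 6 predicted proteins at 89.8% to 97.8%, the most of any glycosyltransferase, and a UDP-glycosyltransferase (ACD03249.1) by 3. The strongest match of this list was a UDP-glucose:glycoprotein glucosyltransferase (XP_020189599.1), which works in protein folding, matched at 95.9% by a predicted protein of 1251 residues. A sterol 3-beta-glucosyltransferase UGT80B1 (XP_020197417.1) followed at 93.9%. ABC transporters of the G family numbered 46, of the C family 28 and of the B family 24. ABC transporter G family members 48 (XP_014752458.1) and 45 (KAE8781511.1) were matched by 4 and 3 proteins. A C family member 8-like transporter (XP_020189736.1) at 92.3% and a G family member 42 (XP_003563764.2) at 96.2% were the strongest matches, by predicted proteins of 1517 and 1493 residues. Of the ABC transporter matches, 3 fell in the accession runs that hold fungal locus tags. The esterase list consisted of 53 GDSL esterases or lipases and 33 carboxylesterases. A GDSL esterase/lipase (AQK78254.1) was matched most often, by 3 predicted proteins at 60.9% to 68.8%, and the strongest matches were an At1g28600-like lipase (XP_020196360.1) at 93.9% and an EXL3 lipase (KAE8775655.1), matched by 2 proteins, at 92.5%. A putative aldo-keto reductase 2 (KAE8810937.1) and an aldo-keto reductase family 4 member C10 (EMS47119.1) matched at 95.1% and 95.2%.

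**Figure D1:**
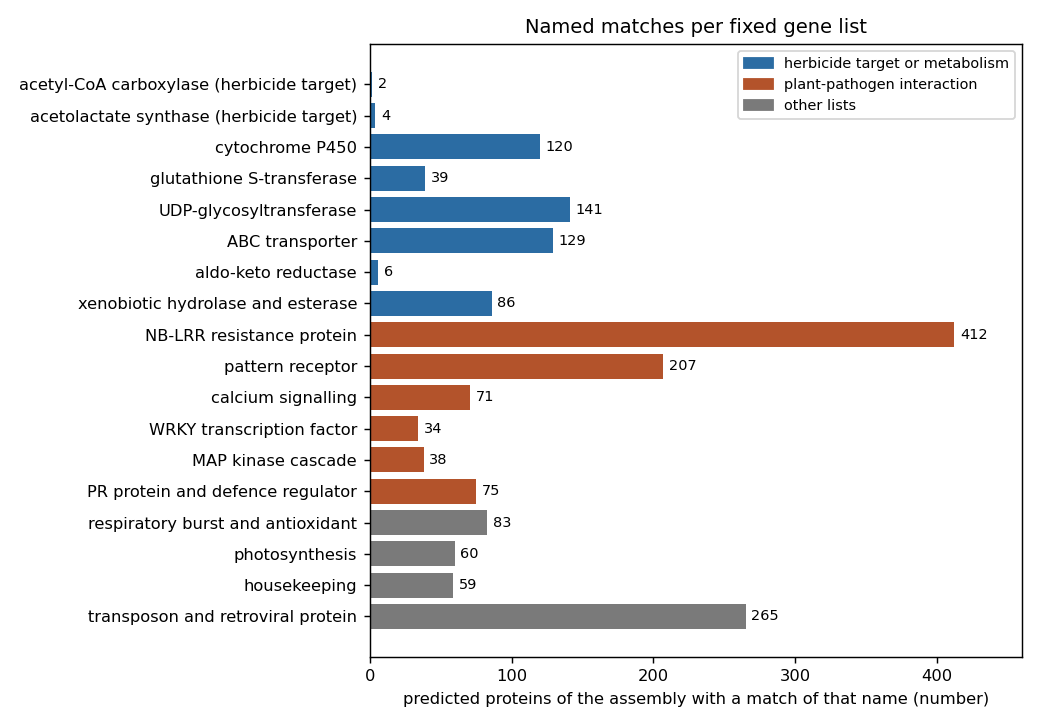
Number of predicted proteins of the pooled assembly whose match carries a name of each of the 18 gene lists, with 1 bar per list and colours for herbicide, plant-pathogen and other lists. NB-LRR resistance proteins form the longest bar at 412, and the herbicide target lists hold 2 and 4.

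The third question concerned plant-pathogen interaction. The 6 defence lists took 837 predicted proteins, 2.12% of the table (exact 95% interval 1.98% to 2.27%), and NB-LRR proteins, the intracellular receptors that recognise pathogen effectors, made up 412 of them. Pattern receptors, which sense microbial molecules at the cell surface, followed with 207. Pathogenesis-related proteins and defence regulators numbered 75, calcium signalling proteins 71, MAP kinase cascade members 38 and WRKY transcription factors 34. Other spellings of the same names, added after the descriptions had been read, raised the NB-LRR count to 564 and the WRKY count to 48. Counting each matched accession once lowered the NB-LRR count to 239, and an E-value of 1e-50 or less lowered it to 251. That E-value also left 123 pattern receptors and 17 WRKY factors. A minimum of 200 residues, chosen after the data were seen, lowered 15 of the 18 lists by more than 1.5-fold, to 212 NB-LRR proteins, 108 pattern receptors and 12 WRKY factors. The whole table shrank as well, from 39502 proteins to 22459 at 1e-50 and to 19463 at this length.

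Under the names fixed in advance, the NB-LRR proteins included 91 named RPM1, 62 RGA4, 51 RGA1, 48 RPP13, and 45 each of RGA2 and RGA3. The fixed spelling missed most RPP13 names, and with the corrected names RPP13 came first with 191, at a median similarity of 79.4%. A putative RGA4 (XP_020174094.1) was matched by 12 predicted proteins at 73.3% to 89.7%, and a putative RGA1 (XP_020195944.1) by 11 at 50.8% to 84.0%. The strongest matches were an RGA3 (XP_020184882.1) at 83.4% and an RGA4 (EMS61584.1) at 79.5%, by predicted proteins of 1755 and 1343 residues. Of the pattern receptors, 125 were LRR receptor-like kinases, 79 were wall-associated kinases and 3 were chitin elicitor receptors. Of the LRR receptor-like kinases, 11 on 10 assembly genes carried the name FLS2, the flagellin receptor. Their median similarity was 76.6%, against 85.95% for all 125, and whether each is a flagellin receptor was not tested. A wall-associated receptor kinase 1 (KAE8791528.1) was matched by 10 predicted proteins at 60.9% to 80.7%, and an LRR receptor-like kinase At3g47570 (XP_020155715.1) by 4.

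Calcium-dependent protein kinases, which carry calcium signals to other proteins, numbered 17, with a median similarity of 96.3%, and cyclic nucleotide-gated channels 7. A further 27 members of the calcium list were named only as binding calmodulin, among them the transcription activators 3 (XP_010228547.1) and 5 (KAE8792500.1) at 91.9% and 92.3%. With these and other names of proteins that only bind, modify or answer to calmodulin dropped, a choice made after reading the descriptions, the list fell from 71 to 38. Among the MAP kinase cascade, 21 proteins were kinases of the uppermost tier, including an NPK1-like kinase (XP_020161801.1) at 93.7%, and a mitogen-activated protein kinase homolog 1 (CAJ85945.1) was matched at 97.8%. The strongest WRKY matches were WRKY 4 (XP_020166589.1) at 86.3% and WRKY 57 (XP_020149447.1) at 88.2%. The defence regulator list held 35 glucan endo-1,3-beta-glucosidases and 13 chitinases, families of which some members cut fungal walls. It also held 10 thaumatin proteins and 6 MLO-like proteins, a family in which loss of a single gene gives mildew resistance in barley. A regulatory protein NPR1 (KAE8769461.1), a salicylic acid sensor, was matched at 86.8%.

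For comparison, 83 proteins belonged to the respiratory burst and antioxidant list, 60 to photosynthesis, 59 to housekeeping and 265 to transposons. The transposon count was 496 with corrected names, 155 with each accession counted once and 109 at an E-value of 1e-50 or less, and the housekeeping count was 43 with corrected names. Respiratory burst oxidases, which make superoxide at the membrane, accounted for 13, with homolog A (XP_003569742.1) matched by 3 predicted proteins and homolog H (XP_020160297.1) by the longest at 776 residues. The P700 apoproteins A1 (YP_009642333.1) and A2 (YP_009642332.1) of photosystem I were matched at 100% by predicted proteins of 751 and 735 residues. A chlorophyll a-b binding protein of LHCII type 1 (XP_010231410.1) was matched by 3 predicted proteins at 97.2% to 99.4%. Polyubiquitin names in the housekeeping list had a median of only 69.8%, whereas the 5 elongation factor 1-alpha proteins had one of 98.5%. Of the housekeeping matches, 3 fell in the accession runs that hold fungal locus tags, among them an elongation factor 1-alpha. The antioxidant list held 2 such matches. A putative retrotransposon protein (ADB85398.1) was matched by 17 predicted proteins at 64.7% to 92.1%.

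The last comparison asked whether each list was closer to, or farther from, its matches than all other proteins of the table. NB-LRR and transposon proteins were farther. The median similarity of NB-LRR proteins was 80.6% against 85.2% for the others, a difference of -4.64 points (95% bootstrap interval -5.55 to -3.45), and 29.9% of them lay above the median of the others. For transposon proteins the difference was -9.53 points (-11.7 to -7.84). Photosynthesis proteins were closer by 13.8 points (10.2 to 14.3), housekeeping proteins by 10.6 (6.51 to 12.5) and ABC transporters by 9.46 (8.65 to 10.4). The adjusted p of the two-sided permutation test over 18 lists was 4.5e-05 for NB-LRR proteins, transposons, photosynthesis and ABC transporters, whose raw p of 1e-05 is the smallest the 100000 permutations can give, and 0.00036 for housekeeping. The size of these differences depended on the background, since proteins with a telling name were closer in general. Set only against such proteins, photosynthesis was closer by 9.325 points, housekeeping by 6.11 and ABC transporters by 5.01. The differences of NB-LRR and transposon proteins were then -9.31 and -14.12 points.

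Respiratory burst and antioxidant proteins (7.23 points, permutation test, adjusted p = 0.0027), calcium signalling proteins (6.79, 0.0085), P450 proteins (5.24, 0.0085) and glycosyltransferases (4.66, 0.0091) were also closer than all other proteins of the table. These 4 calls did not hold under every alternative. Among the alternatives planned in advance, the P450 call was lost at an E-value of 1e-20 or less (2.96 points, permutation test, adjusted p = 0.07) and with accessions counted once (4.02, 0.056). The glycosyltransferase call was lost at 1e-20 (2.08 points, permutation test, adjusted p = 0.19), with assembly genes counted once (2.68, 0.12) and with accessions counted once (3.24, 0.084). The calcium call was lost with genes counted once (4.59 points, permutation test, adjusted p = 0.071). At 1e-50 none of the 4 held, with 2.53 points for the antioxidant list (permutation test, adjusted p = 0.13), 2.79 for calcium (0.15), 1.09 for P450 (0.46) and -0.285 for glycosyltransferases (0.87).

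Among the alternatives chosen after the data were seen, all 4 calls were lost with at least 200 residues. The differences there were 4.53 points for the antioxidant list (permutation test, adjusted p = 0.1), 4.99 for calcium (0.12), 3.18 for P450 (0.18) and 0.79 for glycosyltransferases (0.69). With corrected names the glycosyltransferase call was lost (3.6 points, permutation test, adjusted p = 0.12), whereas the calcium difference grew (9.71, 0.0058). Set only against other proteins with a telling name, all 4 were lost, at 2.77 points for the antioxidant list (permutation test, adjusted p = 0.15), 2.35 for calcium (0.28), 0.76 for P450 (0.66) and 0.175 for glycosyltransferases (0.87). Against that background pattern receptors and WRKY factors fell below the others, by -4.72 points (permutation test, adjusted p = 9e-05) and -8.8 points (adjusted p = 0.004). They did so at 1e-50 as well, by -2.92 points (permutation test, adjusted p = 0.01) and -6.7 points (adjusted p = 0.044). Against all proteins they did not pass the permutation test, at -0.19 points (adjusted p = 0.88) and -4.32 points (adjusted p = 0.23). Glutathione S-transferases (3.56 points, adjusted p = 0.28), esterases (3.45, 0.16), defence regulators (4.13, 0.11) and MAP kinases (3.06, 0.34) did not pass the permutation test either, and the 6 aldo-keto reductases had an adjusted p of 0.18 by the exact permutation test (10.0 points). That list was also too small to pass upward, since its adjusted p with every member at 100% would be 0.059 by the exact test. Proteins of 1 family share sequence and are not independent, and a similarity says nothing of how strongly a gene is expressed.

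**Figure D2:**
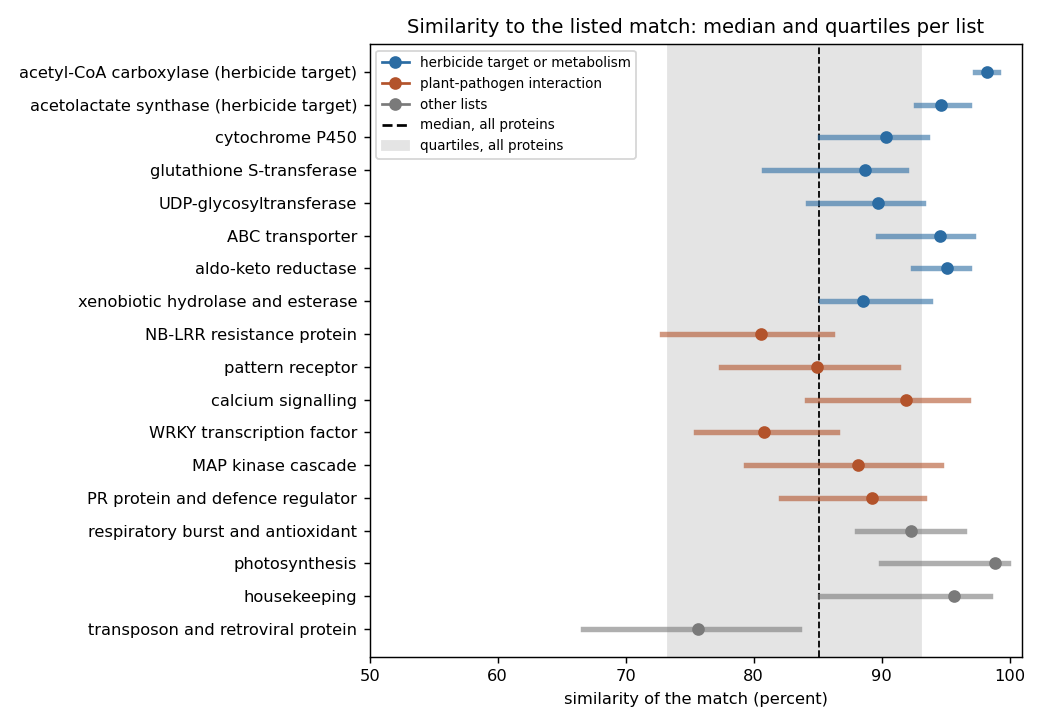
Similarity in percent between predicted proteins and their listed match for each gene list, with the median as a point and the quartiles as a line. The dashed line marks the median of all proteins at 85.1%, and the grey band their quartiles. NB-LRR proteins at 80.6% and transposon proteins at 75.7% lie left of the dashed line, and photosynthesis proteins at 98.9% lie far to the right.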

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

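The matches of 78 predicted proteins carried names that powdery mildew genome projects use, such as the prefixes Bgt and BGHDH14, or names of candidate secreted effectors, the proteins such fungi release into plant cells. None of the gene lists was made for such names, and the count was not tested against an expected one. Together with the accession runs around them, these names make up 296 predicted proteins, 0.749% of the table (exact 95% interval 0.667% to 0.839%), and 9 of them fell in the gene lists, among them the short ACCase protein. Of the tests below, only the one on other proteins of the same transcripts was set before its result was seen.

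A candidate explanation is RNA of a powdery mildew fungus in the leaf material. Proteins of these runs with core cell names, such as ribosomal proteins, had a median similarity of 99.3%, against 94.1% for core-named proteins elsewhere. The difference of 5.2 points (95% bootstrap interval 3.93 to 6.39, permutation p = 0.0003) argues against plant proteins whose listed match is fungal by chance, though the interval includes the 5 points set as the bound. Plant sequences filed under these accessions stay open. Effector names were used to find the runs and so decide nothing. Beyond them, only chitin synthase and septin names were searched for, as kinds of protein that plants lack. Within the runs 1 protein matched, to a septin. A class VII chitin synthase was matched at 96.6% by an accession outside the runs and so was not counted. Other kinds that plants lack were not searched for. The test set beforehand went against the mildew explanation: 100% of the 11 transcripts with further predicted proteins carried a match outside the runs, where under 20% had been predicted. A match outside the runs is not shown to be of another organism, since each run ends at the outermost names used to find it. Those further matches were weak, with a median similarity of 65.6% against 95.4% for the proteins in the runs on the same transcripts. Matches of later proteins were also lower on other transcripts, at 79.7% against 89.9% for the first, so what that test shows of the transcripts' origin stays open. Which sample the transcripts of these proteins came from was not analysed here, and no further biological explanation was tested.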

How the results depend on the processing

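The length, similarity minimum, corrected name, accession run and named background settings were chosen after the data were seen. ABC transporters, photosynthesis, housekeeping, NB-LRR and transposon lists stayed on their side of the threshold under all 9 alternatives, with NB-LRR differences from -9.31 to -4.53 points. The ranges were 4.65 to 9.385 points for ABC transporters, 8.695 to 13.99 for photosynthesis, 6.11 to 10.37 for housekeeping and -14.12 to -7.24 for transposons. Of 160 differences under alternatives, 130 kept direction and side, 18 kept direction and lost the call, 4 gained it, and 8 changed sign, none of them past the threshold after the change. With 1 call among the sign changes, of glycosyltransferases, 19 calls were lost in all. The sign changes at an E-value of 1e-50 or less were glycosyltransferases at -0.285 points, esterases at -0.485 and defence regulators at -0.14. Against telling names they were glutathione S-transferases at -0.9, esterases at -1.04, MAP kinases at -1.4 and defence regulators at -0.335. With accessions counted once, pattern receptors stood at 0.47. The lists above and below the other proteins went from 7 and 2 to 3 and 4 at 1e-50, to 3 above at 200 residues or more, and to 3 and 4 against telling names. At 1e-20 the herbicide and defence shares were 1.52% and 2.33%. At 1e-50 the table held 22459 proteins, 518 of them in defence lists (2.31%), and the herbicide share was 1.74%. At 200 residues or more it held 19463, with 8103 telling names, 296 herbicide (1.52%) and 433 defence proteins. The lower counts follow from the construction, since fewer proteins are kept, but the shares rose. Keeping the strongest match of each assembly gene gave 1.51% and 2.58%, counting accessions once gave 1.76% for defence, and corrected names gave 2.48%. The cause of the moved shares, list numbers and signs was not tested. Of 144 counts per list, 119 stayed within 1.5-fold, 24 were lower and 1, the transposon list with corrected names, was higher. The ACCase list was too small to test under 2 settings. Minimum identity, minimum aligned length, another choice of best match, organism make-up and levels per sample were not run, because the values they need were not used here. No paired analysis was possible because the result comes from no test between samples. Depth is unknown, so what it limits is open.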

Other observations

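Several gene groups outside the lists were also well represented, all chosen after their names were seen. Pentatricopeptide repeat proteins, which process organelle RNA, numbered 388, with a median similarity of 91.9%. F-box proteins, which mark other proteins for breakdown, numbered 324, at a lower median of 79.5%. Lectin receptor kinases numbered 131 and cysteine-rich receptor-like kinases 73, adding to the surface receptors, at medians of 85.6% and 86.3%. FAR1-related proteins, derived from transposases, numbered 80 at 81.6%. Heat shock proteins numbered 44, of which 5 fell in the accession runs with fungal locus tags.

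Matches with names of targets of other herbicides, which the labels do not list, were also found. The D1 protein of photosystem II was matched by 5 predicted proteins at 95.3% to 100%, and glutamine synthetase by 8 at 92.7% to 99.7%. There were 3 proteins each for 4-hydroxyphenylpyruvate dioxygenase, at 84.8% to 91.2%, and phytoene desaturase, at 87.9% to 99.3%, and 2 for protoporphyrinogen oxidase. A single 5-enolpyruvylshikimate-3-phosphate synthase of 427 residues, the glyphosate target, matched at 98.1%. Some transcripts carried several predicted proteins. The one with the most held 13, of which 7 had names of organelle or ribosomal complexes, at a median of 100%, and another held 10 that all had such names, at a median of 99.5%.

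Of the 10 accessions matched most often, the first was an uncharacterized protein (XP_020175238.1) matched by 25 predicted proteins, and 3 were named serine/threonine-protein kinase SMG1, a kinase of RNA quality control. In all, 87 predicted proteins matched 11 accessions of that name, at a median of 78.9%. The test on a split gene was chosen after the result was seen, the one on repeats before. If 1 SMG1 gene had been split by the assembly, its pieces could hardly exceed the longest protein of 3729 residues, but together they were 6.48 times as long. A repeat element inside the matched gene models may be an explanation and cannot be told apart: 0% of 29 transcripts with a further protein carried a transposon name there, against 1.34% of 7565 others (Fisher's exact p = 1), and with so few transcripts the exact interval reaches 11.9%. No biological explanation was tested.

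Several predicted proteins of 1 transcript often matched the same accession. This held for 553 of 7595 transcripts with more than 1 predicted protein, or 7.28%, and the highest share in 100 shuffles was 0.0263%. The test was set before its result was seen. The share lay above all 100 shuffles, as predicted if single proteins were broken over several reading frames. The shuffles removed any relation between proteins of 1 transcript, so other relations would exceed them too. The test therefore cannot single out broken proteins, by which counts of predicted proteins may exceed counts of genes. No biological explanation was tested.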
